A study of Caenorhabditis elegans with 6 samples.

How the data were processed

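RNA was measured in 6 pools of whole CL2006 worms, 3 of the EV control and 3 of nol-56 RNAi, collected on day 6 of adulthood. Per the labels' protocols, polyA-selected libraries were made with a strand-marking mRNA kit and sequenced on an Illumina NovaSeq instrument. Progeny were removed by daily transfer, per the labels. The EV control group was taken from the sample titles and the nol-56 RNAi group from the treatment label. Replicate numbers were taken from the sample titles. Nothing in the labels says that the pools came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The permutation p-values near the end are over genes instead.

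The deposited table gives the authors' whole-number read count per gene and library, with no normalization, and a normalized value per gene and library. The submitters' processing notes name cutadapt 2.10, TopHat2 2.1.1, HTSeq 2.01, DESeq2 1.36.0 and the genome build WBcel235, with no role or order, and the strand setting of the counting is not given in the sources used here. If strand was not used in counting, reads of overlapping or antisense genes cannot be told apart. The authors' normalized values are a signal equal to the count divided by 1 size factor per library (0.832, 1.23 and 1.16 in EV control libraries 1 to 3 and 1.02, 1.00 and 0.882 in nol-56 RNAi libraries 1 to 3). They were given for 18086 genes, those with a total count of at least 10. Normalized values were used only to check the size factors.

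The table has 46934 rows, of which 22416 hold counts: 19984 protein-coding genes, 2128 pseudogenes, 194 lincRNAs and 100 antisense RNAs, and 10 genes with no match in the annotation. The other 24518 rows hold no counts and are annotated as small or structural RNA classes, with 15363 piRNA genes as the largest, and none as protein coding. No row was without a gene identifier. Gene positions and types were taken from the Ensembl 115 annotation of WBcel235, in which 22406 of the genes with counts were found. The counts were taken as deposited. Total counts per library were 21138955 to 34841215, which gives small counting error for all but weakly expressed genes, and the filter kept at least 99.9% of the counts in each library. Counts of PCR-amplified reads without molecular identifiers are not counts of independent molecules.

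Tests used R 4.3.3, edgeR 4.0.16 and limma 3.58.1. Genes were filtered with filterByExpr at its default settings, scaled with TMM factors and fitted with edgeR's quasi-likelihood model with the group as the only term. P-values were two-sided and adjusted with the Benjamini-Hochberg method, with a threshold of 0.05. Fold changes are nol-56 RNAi over EV control. CPM values use TMM-scaled library sizes, and log2 CPM for correlations and principal components a prior count of 2. Each pair of libraries within a group was compared with a chi-square test over genes, and every pair differed by more than sampling noise (chi-square per degree of freedom 2.08 to 6.39), so none was counted as a repeated library.

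Gene lists were written out before the data were examined, as were the main test, the rule for named genes and the alternatives. Each of the 34 lists was tested with camera, which compares its genes with all others, at a preset inter-gene correlation of 0.01, with adjustment over all lists, and again with an estimated correlation. Some written names had no match in the gene names used (10 biogenesis factors, 4 intracellular pathogen response genes, 2 translation factors and 1 in each of 7 other lists) and were left out. The lists share few genes, at most 4 for any pair. The text names nol-56, fib-1 and nol-58. It then names the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold, with a mean log2 CPM of at least 3 and groups that do not overlap. Up to 4 genes of each list with the smallest p follow, and a fixed set of TGF-β, ERK, stress and reporter genes whatever their values. Genes named outside this rule are said to have been chosen after their values were seen. The planned comparison with the authors' own fold changes was not run, because no columns of that kind were analysed here.

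The tests were run on simulated counts with known changes, drawn from the means and library sizes of this comparison. Far fewer genes were changed there than were called in the real comparison. Of 14353 genes tested there, edgeR recovered 24 of 48 genes changed 1.25-fold, 34 of 48 changed 1.5-fold, 43 of 48 changed 2-fold and 49 of 49 changed 4-fold, and called 9 of 14160 unchanged genes. Alternatives were RLE and upper-quartile factors and library totals, no filter, CPM above 5 in at least 3 libraries, the replicate number as a block, each library left out, the 20 genes with the most counts left out, DESeq2 1.42.0, limma-voom, glmTreat against a fold of 1.5, a fold of at least 2, fry, and camera on ranks.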

Results

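Whole-animal transcriptomes were measured by polyA-selected RNA sequencing in CL2006, a transgenic Caenorhabditis elegans strain in which a muscle promoter, that of unc-54, drives the human amyloid-β peptide. Pools of whole worms were collected on day 6 of adulthood after culture at 20 °C. From the last larval stage onward, 3 pools were fed bacteria carrying the empty RNAi vector (EV control) and 3 were fed bacteria expressing double-stranded RNA against nol-56. The total gene count per library was 24109520, 34841215 and 31843364 in EV control libraries 1 to 3 and 23901618, 23829574 and 21138955 in nol-56 RNAi libraries 1 to 3, with 18988 to 19454 genes detected in each. Libraries of one group had Pearson correlations of 0.995 to 0.996 in log2 CPM, the counts scaled to a common library total, across genes, against 0.939 to 0.944 between groups, and the first principal component, which separated the groups, held 91.1% of the variance. The comparison of nol-56 RNAi with EV control asks how the loss of a nucleolar protein alters gene expression, with the TGF-β and ERK signalling pathways and protein homeostasis as the stated interest of the study.

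The nol-56 transcript fell 14.4-fold on nol-56 RNAi, from 263 ± 8.67 to 18.2 ± 2.59 CPM (mean ± SD, n = 3 libraries per group). nol-56 encodes a core protein of the box C/D small nucleolar ribonucleoprotein, which guides methylation of ribosomal RNA. The transcripts of partner proteins in this complex fell as well: fib-1, the fibrillarin methyltransferase, by 2.94-fold, nol-58 by 1.66-fold and M28.5 (snu-13), named after its values were seen, by 1.80-fold. The falls of nol-58 and M28.5 were near the median fall of the ribosome biogenesis list (1.68-fold) and below that of germline markers (1.94-fold). Across the transcriptome, markers of the germline and the embryo, ribosome biogenesis factors, translation factors, proteasome subunits and mitochondrial chaperones were lower, and markers of neurons, muscle, pharynx and intestine, yolk proteins, immune effectors and detoxification enzymes were higher. The calls on lists rest on camera's preset correlation: with an estimated correlation 0 of 34 passed (lowest adjusted p = 0.0751; 9 with an unadjusted p under 0.05). The embryo call was also lost with genes above 5 CPM alone (adjusted p = 0.745).

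The gene nol-56 (WBGene00010627) is protein coding and spans chromosome V, 10350466 to 10352978, on the minus strand of WBcel235. Its raw count was 5878, 9029 and 8288 in EV control libraries 1 to 3 and 518, 442 and 339 in nol-56 RNAi libraries 1 to 3, so the targeted gene followed the sample labels in every library. Its log2 fold change was −3.85 with a standard error of 0.06 (adjusted p = 1.18e-21, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, two-sided). fib-1 (WBGene00001423, chromosome V, 15000651 to 15002223) went from 421 ± 3.76 to 144 ± 7.78 CPM, a log2 fold change of −1.55 with a standard error of 0.04. nol-58 (WBGene00020915, chromosome I, 3267094 to 3269112) went from 398 ± 9.99 to 240 ± 2.07 CPM, a log2 fold change of −0.73 with the same standard error.

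**Figure D1:**
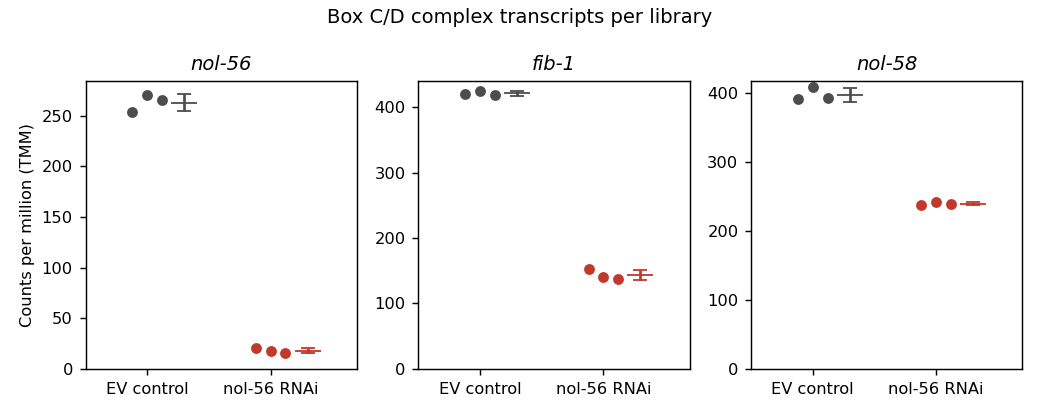
TMM-scaled CPM of nol-56, fib-1 and nol-58 in each library of EV control and nol-56 RNAi; points are libraries, and the horizontal mark with bars is the mean ± SD (n = 3). For nol-56, the EV control libraries lie between 253 and 270 CPM and the nol-56 RNAi libraries between 15.7 and 20.8 CPM, and the groups do not overlap for fib-1 or nol-58 either.

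Of 14677 genes tested, 6927 were higher and 5990 lower on nol-56 RNAi at an adjusted p under 0.05, and 1760 did not pass the threshold. A change of at least 2-fold was seen in 3633 of the higher and 1823 of the lower genes, and one of at least 4-fold in 145 and 405. The groups did not overlap in 12918 genes (88.0%), where chance gives 10%. The calls rest on replicates that varied by a biological coefficient of variation of 3.93%, so that small changes passed the test. The split of calls depends on the scaling: 53.6% of calls were higher with TMM factors, 49.6% with RLE factors and 62.4% with upper-quartile factors. The median log2 fold change of all genes moved from 0.16 with TMM by −0.14 with RLE factors and by 0.25 with upper-quartile factors.

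The 10 largest increases among well-expressed genes whose groups did not overlap were led by F54F7.2, which rose 7.96-fold from 11.07 ± 1.07 to 88.4 ± 1.71 CPM (chromosome X, 11843663 to 11845337). The saposin-like gene spp-9 rose 6.77-fold, from 7.01 ± 0.886 to 47.7 ± 3.56 CPM (chromosome X, 11487784 to 11488203), and the aspartyl protease gene asp-17 rose 5.69-fold, from 22.8 ± 0.651 to 130.2 ± 1.83 CPM (chromosome V, 19035723 to 19037322). The others were ZK380.6 (5.46-fold), drd-10 (5.28-fold), sdz-27 (4.42-fold), F15E6.4 (4.41-fold), the collagen gene col-183 (4.32-fold), Y47H9C.1 (4.30-fold) and scl-24 (4.23-fold). After nol-56, the largest decreases were those of the cuticlin-like gene cutl-16, which fell 8.83-fold from 68.5 ± 3.45 to 7.80 ± 1.39 CPM (chromosome II, 6441428 to 6443994), and the C-type lectin gene clec-266, which fell 7.91-fold from 149 ± 4.14 to 18.8 ± 0.691 CPM (chromosome X, 6617393 to 6622915). car-1, which encodes an RNA-binding protein of germline granules, went from 1675 ± 17.4 to 243 ± 10.8 CPM (log2 fold change −2.78; chromosome I, 12904470 to 12906040), and the caveolin gene cav-1 from 270.2 ± 17.7 to 37.9 ± 3.33 CPM (−2.83; chromosome IV, 9772510 to 9773559). C39B5.2 (−2.90), vet-2 (−2.83), ttr-50 (−2.78) and the innexin gene inx-2 (−2.76) completed the group with prg-2 (−2.78), whose value is uncertain because it shares sequence with the near-identical prg-1.

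Germline transcripts were lower. Of 40 germline and oocyte markers, 38 fell and 2 rose, with a median log2 fold change of −0.96 (camera adjusted p = 2.97e-15; adjusted p = 0.185 with an estimated correlation). The meiotic chromosome axis gene htp-3 fell from 164 ± 2.55 to 39.8 ± 1.46 CPM (−2.05), and glh-2 (−1.51) and pgl-3 (−1.60), which encode germ granule components, and the egg surface receptor gene egg-2 (−1.27) fell too. The 2 that rose, named after their values were seen, were the eggshell genes perm-2 (0.95) and perm-4 (1.04). Among 36 early zygotic embryo markers with enough reads, 29 fell and 6 rose, with a median of −2.34 (camera adjusted p = 0.0123; adjusted p = 0.446 with an estimated correlation); vet-6 (−3.62) and tbx-9 (−1.54) fell while sdz-27 rose. With only genes above 5 CPM in at least 3 libraries this call was lost and the median was −0.42 (adjusted p = 0.745, in a range of 0.00216 to 0.745 over the alternatives with camera). The list's share of all counts was 0.040 ± 0.0011% in EV control and 0.048 ± 0.0006% in nol-56 RNAi libraries, with sdz-27 going from 59.8 ± 1.05 to 264 ± 2.82 CPM. Without sdz-27 the share went from 0.035 ± 0.0011% to 0.021 ± 0.0004%. Sperm markers had a median of −2.30, with 18 lower and 5 higher of 25, and the list did not pass the test (camera adjusted p = 0.291). The share of all counts held by the sperm list was 0.004% in EV control and 0.004% in nol-56 RNAi libraries. Levels were low, with msp-57 at 1.22 CPM in EV control and 0.096 CPM in nol-56 RNAi. msp-57 (−3.61) and msp-50 (−3.24) fell and ssp-37 (0.77) rose, but the msp genes are near-identical copies whose reads cannot be assigned with certainty.

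Markers of most somatic tissues were higher. Of 58 neuron markers, 56 rose and none fell (median 1.24, camera adjusted p = 8.22e-12; adjusted p = 0.0751 with an estimated correlation), among them the neuropeptide-processing genes egl-3, from 107 ± 3.28 to 290 ± 11.11 CPM (1.44), and egl-21 (1.46). Body wall muscle markers rose in 23 of 26 cases (median 0.90, camera adjusted p = 2.86e-09; adjusted p = 0.162 with an estimated correlation), with unc-27 (1.12), mlc-3 (1.11) and mlc-2 (1.15) among them. The myosin gene unc-54 rose from 1184 ± 82.8 to 2091 ± 23.7 CPM (0.82); its reads and those of rol-6 may include transcripts of the strain's transgenes, which were not analysed here. Pharynx markers rose in 11 of 14 cases (median 1.04, camera adjusted p = 0.00273; adjusted p = 0.185 with an estimated correlation), led by the pharyngeal myosins myo-2 (1.44) and myo-1 (1.42). Of 23 intestine markers, 22 rose and 1 fell (median 0.98, camera adjusted p = 2.46e-07; adjusted p = 0.185 with an estimated correlation), including the cysteine protease genes cpr-3 (1.41) and cpr-4 (1.15). Epidermis and seam markers went the other way in the larger part, with 13 lower, 7 higher and 3 not past the threshold (median −0.52), and the list did not pass the test (camera adjusted p = 0.393). The apical matrix genes noah-2 (−1.66) and noah-1 (−1.38) and the hedgehog-related gene wrt-10 (−2.07) fell, and the cuticle collagen gene rol-6 (1.11) rose.

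**Figure D2:**
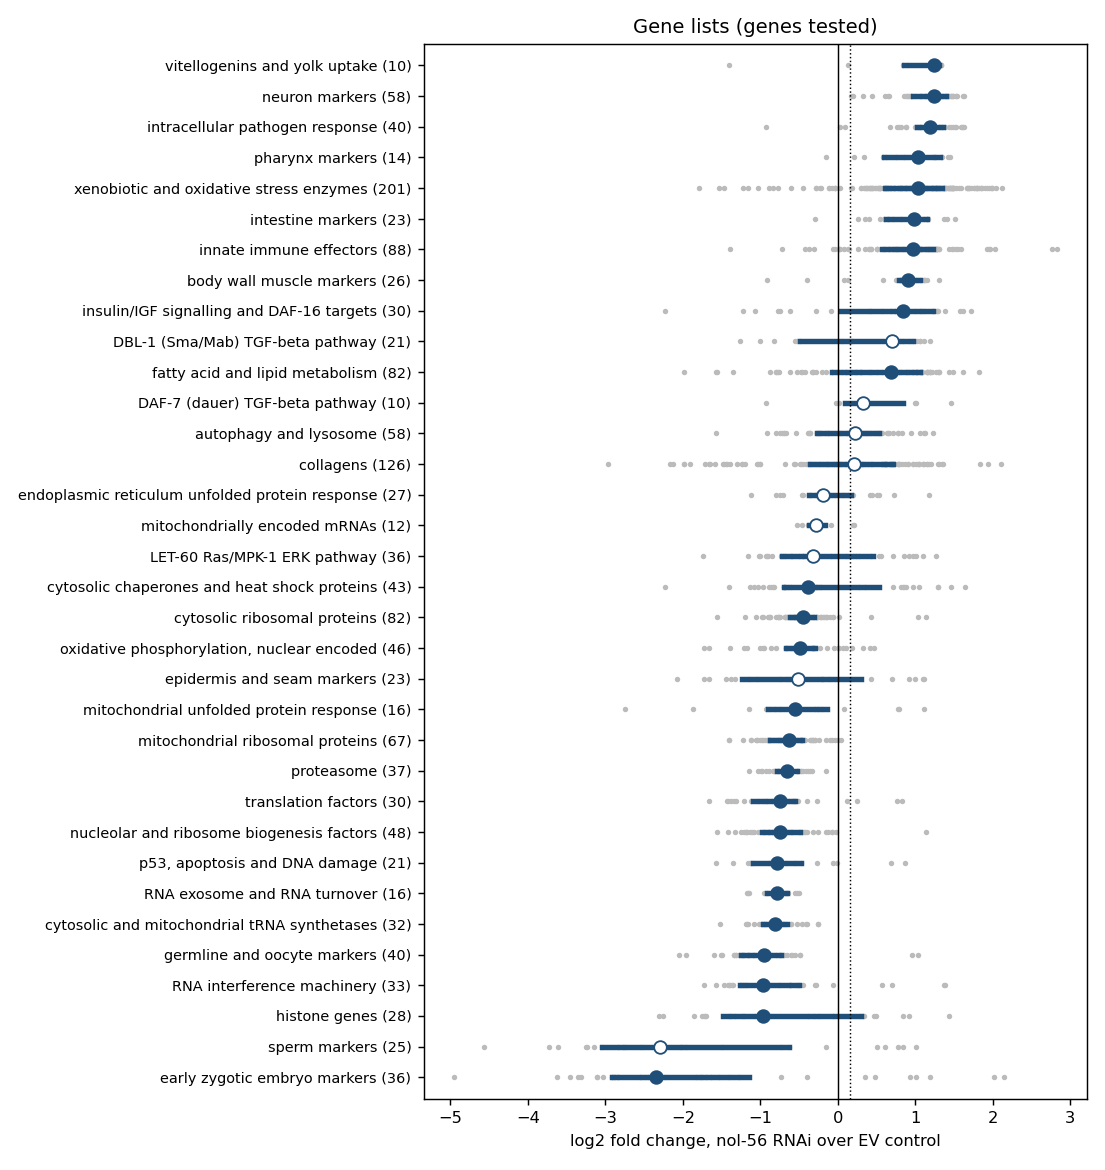
Log2 fold change, nol-56 RNAi over EV control, of the genes in each of the 34 lists, with the number of genes tested in brackets. Grey dots are genes, the bar spans the interquartile range and the circle is its median, filled where the camera adjusted p with the preset correlation was under 0.05; the dotted line is the median of all genes tested, 0.16. Germline and biogenesis lists lie to the left of it and neuron, muscle, pharynx and intestine markers to the right.

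Genes that make ribosomes and proteins were lower together. Of 48 genes in the nucleolar and ribosome biogenesis list, 44 fell and 1 rose (median −0.75, camera adjusted p = 3.55e-11, and 0.162 with an estimated correlation). The list was matched by symbol, and these counts include gar-1 and nop-1, named after their values were seen. In C. elegans these symbols belong to an acetylcholine receptor gene and a pseudocleavage gene. gar-1 (1.14) was the 1 that rose, and nop-1 (−1.10) fell. dao-5 (−1.42) and the AAA ATPase genes ruvb-1 (−1.32) and ruvb-2 (−1.17) fell with fib-1. All 32 aminoacyl-tRNA synthetases fell (median −0.81, camera adjusted p = 1.74e-09; adjusted p = 0.185 with an estimated correlation), as kars-1 (−1.17) and ears-1 (−1.19) did. Of 30 translation factors, 26 fell and 4 rose (median −0.74, camera adjusted p = 1.63e-08; adjusted p = 0.185 with an estimated correlation), with eif-3.C (−1.43) and iff-1 (−1.66) among the former. Cytosolic ribosomal proteins fell in 74 of 82 cases and rose in 3 (median −0.45, camera adjusted p = 1.98e-06; adjusted p = 0.482 with an estimated correlation). Their share of all counts went from 6.45 ± 0.271% to 4.98 ± 0.239%. rpl-11.1 (−1.55) and rpl-7A (−1.20) fell while rpl-25.1 (1.04) rose. Of 67 mitochondrial ribosomal proteins, 62 fell and none rose (median −0.63, camera adjusted p = 2.63e-07; adjusted p = 0.127 with an estimated correlation), for example mrps-22 (−1.40) and mrpl-11 (−1.22). The germline markers beside these lists had a median of −0.96, lower than that of each of them.

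RNA and protein turnover genes moved the same way. All 16 members of the RNA exosome and RNA turnover list fell (median −0.79, camera adjusted p = 5.05e-06; adjusted p = 0.112 with an estimated correlation), with the helicase gene mtr-4 (−1.16) and the exonuclease gene xrn-2 (−1.17) among them. All 37 proteasome genes fell (median −0.66, camera adjusted p = 1.74e-09; adjusted p = 0.219 with an estimated correlation), including rpn-1 (−1.14) and rpt-3 (−1.03). The RNA interference machinery was lower in 28 of 33 genes and higher in 4 (median −0.96, camera adjusted p = 1.74e-09; adjusted p = 0.185 with an estimated correlation), with the Argonaute genes wago-4 (−1.72), wago-1 (−1.41) and csr-1 (−1.25) and the RNA-dependent RNA polymerase gene ego-1 (−1.40) falling. Of 21 genes of the p53, apoptosis and DNA damage list, 17 fell and 2 rose (median −0.78, camera adjusted p = 2.71e-05; adjusted p = 0.185 with an estimated correlation), among them the checkpoint kinase gene atm-1 (−1.58) and the p53 homolog cep-1 (−1.16). Of 75 histone genes, only 28 had enough reads in these polyA-selected libraries. Among these 28, 18 fell and 7 rose (median −0.97, camera adjusted p = 0.0401, and 0.185 with an estimated correlation). The linker histone gene his-24 (−1.75) fell. The histone call was lost without nol-56 RNAi library 3 (adjusted p = 0.0517), with genes above 5 CPM alone (median −0.24, adjusted p = 0.111) and on ranks (adjusted p = 0.0553), in a range of 0.0208 to 0.185 over the alternatives with camera. Many of these genes are expressed in the germline, whose markers had a median of −0.96.

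The TGF-β and ERK lists held changes in both directions. In the DBL-1 (Sma/Mab) list 13 of 21 genes rose and 6 fell, and in the DAF-7 (dauer) list 7 of 10 rose and 1 fell. Medians were 0.70 and 0.33, and neither list passed the test against other genes (camera adjusted p = 0.103 and 0.202). The ligand gene daf-7 rose 2.75-fold, from 5.68 ± 0.293 to 15.6 ± 0.947 CPM (1.46), whereas the ligand gene dbl-1 stood at 0.05 (adjusted p = 0.599). The receptor genes daf-1 (−0.93) and daf-4 (−0.55) fell, whereas the receptor gene sma-6 (0.80), named after its values were seen, rose. The Smad gene sma-3 (1.11) and the co-Smad gene sma-4 (1.19) rose, and daf-3, the co-Smad gene of the dauer branch, stood at 0.02 (adjusted p = 0.741). With upper-quartile factors dbl-1 (0.30) and daf-3 (0.27) passed the threshold as higher (adjusted p = 0.00329 and 8.87e-05), as they did with genes above 5 CPM alone (0.0368 and 0.00667) and daf-3 with library totals (0.0475). With RLE factors they stood at −0.09 and −0.12, and the highest adjusted p over the alternatives was 0.945 and 0.971. lon-1, a target that DBL-1 signalling represses, rose from 89.1 ± 3.14 to 185 ± 1.94 CPM (1.05), crm-1 (1.02) and the nuclear receptor gene daf-12 (1.01) rose, and tsp-12 (−0.83) fell. In the LET-60 Ras/MPK-1 ERK list 20 of 36 genes fell and 12 rose (median −0.32, camera adjusted p = 0.103; 0.0387 with no filter on low counts). Along the kinase cascade, the Raf gene lin-45 fell from 240.2 ± 15.4 to 158 ± 4.13 CPM (−0.60) and the ERK gene mpk-1 from 212 ± 7.31 to 128 ± 2.75 CPM (−0.73). The MEK gene mek-2 fell by 0.31 on the log2 scale with TMM and stood at −0.06 with upper-quartile factors (adjusted p = 0.145), and the Ras gene let-60 stood at −0.09 (adjusted p = 0.0622), and with upper-quartile factors it was called higher (0.16, adjusted p = 0.00158). let-60 passed the threshold as lower with RLE factors (−0.23, adjusted p = 0.000209) and with DESeq2 (−0.25, adjusted p = 4.96e-05). It also passed without EV control library 2 (adjusted p = 0.0496), EV control library 3 (0.0136) or nol-56 RNAi library 3 (0.0323). The highest adjusted p over the alternatives was 0.937. The phosphatase gene ptp-2 (−1.73) and the Mediator subunit gene sur-2 (−1.17) had the smallest p in the list. Germline markers (median −0.96) and neuron markers (median 1.24) moved apart in the same libraries.

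**Figure D3:**
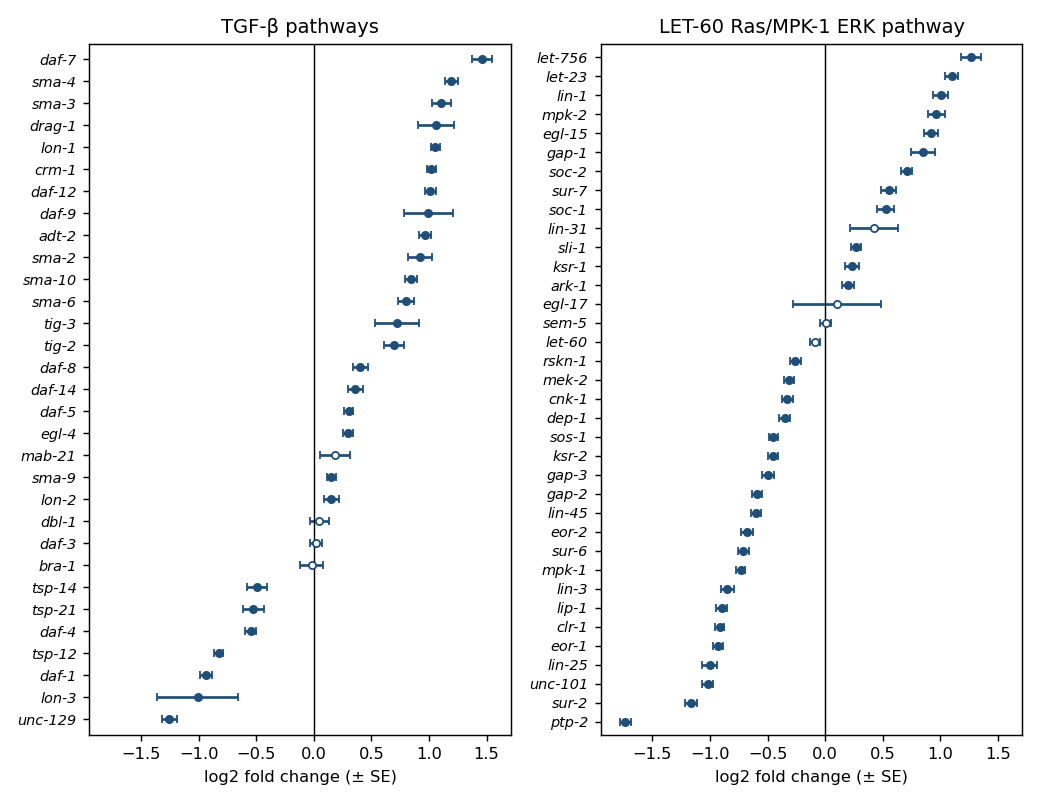
Log2 fold change (± standard error, n = 3 libraries per group), nol-56 RNAi over EV control, of each gene tested in the DBL-1, DAF-7 and LET-60/MPK-1 lists; filled symbols passed an adjusted p of 0.05 in the edgeR test. Genes of each list lie on both sides of 0, with daf-7 at 1.46, sma-4 at 1.19, daf-1 at −0.93 and ptp-2 at −1.73. let-60 changes sign with upper-quartile factors, library totals and genes above 5 CPM alone. dbl-1 and daf-3 change sign with RLE factors and DESeq2. daf-3 also does so without EV control library 2 or nol-56 RNAi library 3.

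Chaperone transcripts were lower in the larger part. Of 43 cytosolic chaperones and heat shock proteins, 29 fell and 12 rose (median −0.38, camera adjusted p = 0.00566; adjusted p = 0.303 with an estimated correlation). The small heat shock protein gene sip-1 fell from 2767 ± 92.0 to 588 ± 20.4 CPM (−2.23). The chaperonin genes cct-8 (−1.41) and cct-6 (−1.13) and the co-chaperone gene sti-1 (−1.08) fell, and so did the heat shock factor gene hsf-1, from 167 ± 12.81 to 91.7 ± 2.69 CPM (−0.86). The stress-inducible hsp-16.2 rose (0.72). The 12 that rose also include hsp-17 (1.46), hsp-25 (1.04), hsp-43 (0.97) and hsp-70 (0.84), named after their values were seen. Small heat shock protein genes thus went both ways. In the mitochondrial unfolded protein response list 12 of 16 genes fell and 3 rose (median −0.56, camera adjusted p = 0.00167; adjusted p = 0.127 with an estimated correlation). Both mitochondrial chaperones were much lower: hsp-60 fell 6.74-fold, from 474 ± 8.47 to 70.4 ± 2.15 CPM (−2.75), and hsp-6 fell 3.66-fold, from 839.9 ± 19.4 to 229.5 ± 3.07 CPM (−1.87). The mitochondrial protease gene lonp-1 (−0.93) and atfs-1 (−0.89), the transcription factor of this response, fell too. The endoplasmic reticulum list had 16 lower and 8 higher of 27 and did not pass the test (camera adjusted p = 0.419); its median was −0.19 and 0.06 with upper-quartile factors. atf-4 (1.17) rose, while ire-1 (−0.75), cnx-1 (−0.80), dnj-28 (−1.12) and the BiP gene hsp-4 (−0.36) fell. Of 58 autophagy and lysosome genes, 34 rose and 20 fell (median 0.22, camera adjusted p = 0.122), a list that passed the test with upper-quartile factors (adjusted p = 0.00833) and with genes above 5 CPM alone (0.0356); the cathepsin genes cpl-1 (1.12) and asp-4 (1.22) rose and epg-2 (−1.57) fell. The germline median beside these lists was −0.96.

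Immune and detoxification genes were higher. Of 88 innate immune effectors, 74 rose and 3 fell (median 0.97, camera adjusted p = 1.74e-09; adjusted p = 0.108 with an estimated correlation), with irg-7 (1.28) and sysm-1 (1.17) rising beside spp-9 and the lectin gene clec-87 (−1.39) falling. In the intracellular pathogen response list 37 of 40 genes rose and 1, the RNA sensor gene drh-1 (−0.93), fell (median 1.19, camera adjusted p = 8.97e-05; adjusted p = 0.127 with an estimated correlation); eol-1 (1.20), and cul-6 (1.31) and skr-3 (1.06), which encode ubiquitin ligase subunits, rose. Xenobiotic and oxidative stress enzymes rose in 173 of 201 cases and fell in 15, or 174 and 15 adjusted over the list alone (median 1.03, camera adjusted p = 1.74e-09; adjusted p = 0.0751 with an estimated correlation). The glucuronosyltransferase gene ugt-25 rose from 44.1 ± 1.26 to 168 ± 3.89 CPM (1.93), and ugt-63 (1.80), ugt-41 (1.72) and the transporter gene pgp-2 (1.37) rose. Intestine markers, measured in the same libraries, had a median of 0.98.

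Metabolic and extracellular groups included the most abundant transcripts. Vitellogenin genes, which encode yolk proteins made in the intestine, took 5.70 ± 0.106% of all counts in EV control and 14.9 ± 0.893% in nol-56 RNAi libraries (n = 3). Of 10 vitellogenin and yolk uptake genes 9 rose and 1 fell (median 1.24, camera adjusted p = 0.00106; adjusted p = 0.185 with an estimated correlation). vit-2 rose from 13810 ± 503.7 to 34630 ± 2476 CPM (1.33), vit-5 (1.33) and vit-6 (1.27) rose, and the oocyte yolk receptor gene rme-2 (−1.41) fell. Without the 20 genes with the most counts, which include vit-2, vit-4, vit-5 and vit-6, the list did not pass the test (adjusted p = 0.221). Fatty acid and lipid genes rose in 58 of 82 cases and fell in 19 (median 0.69, camera adjusted p = 0.000209; adjusted p = 0.185 with an estimated correlation), with acs-22 (1.44) and the desaturase gene fat-5 (1.31) rising and lbp-9 (−1.98) and acdh-13 (−1.57) falling. Of 30 genes of insulin/IGF signalling and DAF-16 targets, 22 rose and 7 fell (median 0.84, camera adjusted p = 0.0384, and 0.219 with an estimated correlation). The ferritin gene ftn-1 (1.71), dod-19 (1.38) and the gluconeogenic gene pck-1 (1.28) rose. So did sod-3 (0.99), at a low level (2.01 CPM in EV control and 4.03 CPM in nol-56 RNAi). sip-1 (−2.23), which had the smallest p in the list, fell. The list mixes pathway genes with targets that DAF-16 raises and targets that it lowers, such as dod-19. Its median therefore does not measure DAF-16 activity. The list's share of all counts went from 0.768 ± 0.0231% to 0.664 ± 0.0187%, and without sip-1 from 0.50 ± 0.0174% to 0.603 ± 0.0203%. That call was lost without EV control library 3 (adjusted p = 0.0538) and with genes above 5 CPM alone (adjusted p = 0.0522), in a range of 0.0113 to 0.219 over the alternatives with camera. The transcription factor gene daf-16 itself stood at −0.09 (adjusted p = 0.0746), and with upper-quartile factors it was called higher (0.16, adjusted p = 0.00139). It passed the threshold as lower with RLE factors (−0.23, adjusted p = 0.000251), with DESeq2 (−0.25, adjusted p = 2.42e-05) and without EV control library 3 (adjusted p = 0.00278); the highest adjusted p over the alternatives was 0.876. skn-1 fell by 0.30 on the log2 scale with TMM and stood at −0.05 with upper-quartile factors (adjusted p = 0.212). Collagens rose in 52 and fell in 33 of 126 cases, or 50 and 33 adjusted over the list alone, and did not pass the test (median 0.21, camera adjusted p = 0.161); the basement membrane collagens let-2 (1.30) and emb-9 (1.15) rose. Somatic marker medians other than that of the epidermis were 0.90 to 1.24.

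Nuclear-encoded oxidative phosphorylation genes were lower in 36 of 46 cases and higher in 4 (median −0.49, camera adjusted p = 5.84e-05; adjusted p = 0.351 with an estimated correlation). The ATP synthase genes asb-1 (−1.73), atp-1 (−1.39) and atp-2 (−1.21) and the complex I gene nduf-2.2 (−1.66) fell. Germline markers in the same libraries had a median of −0.96. Of 12 mRNAs encoded in mitochondrial DNA, 9 fell and 2 rose (median −0.29, camera adjusted p = 0.544), and their share of counts was 0.773 ± 0.026% in EV control and 0.825 ± 0.122% in nol-56 RNAi libraries. nduo-2 (−0.52) fell; nduo-1 fell by 0.20 on the log2 scale with TMM and stood at 0.05 with upper-quartile factors, and ctc-2 (−0.36), nduo-4 (−0.34) and nduo-6 (−0.46) did not pass the test with those factors. Without nol-56 RNAi library 1 nduo-1 was not past the threshold either (adjusted p = 0.0619, in a range of 2.81e-07 to 0.461 over the alternatives).

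In all, 25 of the 34 lists passed the camera test with the preset correlation, 10 higher and 15 lower. With an estimated correlation 0 passed, at adjusted p from 0.0751 to 0.841, and 9 had an unadjusted p under 0.05; fry, which asks only whether the genes of a list move one way, called 32. For every list except the xenobiotic enzymes and collagens, the counts adjusted over the list alone were equal to those over all genes tested.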

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

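No alternative was added after the data were seen. The log2 fold change of nol-56 stayed past the threshold with its direction under every alternative that tested it. The number of higher genes was 4508 with CPM above 5 in at least 3 libraries, where fewer genes were tested, and 3633 at 2-fold or more. The number of lower genes was 3236 with glmTreat against a fold of 1.5 and 1823 at 2-fold or more. These fall by construction, as the conditions are stricter. The other alternatives gave counts within 1.5 times the main ones, among them RLE factors with 6362 higher and 6467 lower genes, upper-quartile factors with 8002 and 4825, and DESeq2 with 5765 and 6539. Leaving out each library gave 6742 to 6937 higher and 5933 to 6056 lower genes, a nol-56 log2 fold change of −3.96 to −3.76, and 24 to 25 lists. Of the lists, 0 passed with an estimated correlation, 9 having an unadjusted p under 0.05, against 25 with the preset one, 32 with fry and 24 with camera on ranks. Signs reversed, with a call on one side or both, for 3 named genes, all with upper-quartile factors: let-60 to 0.157, daf-16 to 0.161 and nduo-1 to 0.049. This follows the shift of 0.25 in the median of all genes under those factors. Over all settings, named genes kept their side of the threshold 2459 times (10 of these with another sign, not called in either setting), gained a call 13 times and lost one 8 times; single lists did so 501 (1 with another sign), 10 and 32 times. The replicate block gave 6893 higher and 5964 lower genes, a nol-56 log2 fold change of −3.85 and 25 lists. Deviations of libraries with the same number correlated at −0.035, −0.011 and 0, and 0 of 6 libraries correlated best with their own number, so the numbers were not taken to pair samples. Depth may limit weakly expressed genes and small changes, which was not tested. The simulation recovered 34 of 48 changes of 1.5-fold, but it did not vary depth. It left 14160 of 14353 genes unchanged, whereas 88.0% of genes were called in the real comparison, so it does not give the power of that comparison.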

Other observations

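The families, gene pairs and chromosomes below were chosen after the results were seen, and in the same libraries germline markers had a median log2 fold change of −0.96, neuron markers 1.24 and intestine markers 0.98. Transthyretin-related (ttr) genes were higher in 45 of 48 cases (median 1.20, camera adjusted p = 6.6e-11; adjusted p = 0.0583 with an estimated correlation). Neuropeptide-like (nlp) genes were higher in 66 of 70 (median 1.26, camera adjusted p = 3.53e-08; adjusted p = 0.0583 with an estimated correlation). All 25 nucleoporin (npp) genes were lower (median −0.91, camera adjusted p = 5.51e-10; adjusted p = 0.191 with an estimated correlation). F-box B (fbxb) genes were lower in 81 of 84 cases, with a median of −2.72 (camera adjusted p = 0.000202; adjusted p = 0.314 with an estimated correlation); they form a large family of similar genes whose reads are uncertain. Carboxylesterase (cest) genes were higher in 29 of 32 (median 1.08, camera adjusted p = 3.57e-05; adjusted p = 0.191 with an estimated correlation).

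Several pairs of related genes moved apart, and pairs were not counted. Others fell together, such as rpl-41.1 (−0.74) with rpl-41.2 (−0.68) and eef-1B.1 (−0.63) with eef-1B.2 (−0.66). The ATP synthase subunit gene asb-1 went from 257 ± 3.70 to 77.7 ± 4.37 CPM, whereas asb-2 went from 148 ± 6.42 to 184 ± 1.89 CPM (mean ± SD, n = 3). The translation factor gene iff-1 went from 417 ± 23.03 to 132 ± 7.59 CPM and iff-2 from 167 ± 8.04 to 282 ± 11.06 CPM. The ribosomal protein gene rpl-11.1 went from 811 ± 43.1 to 276 ± 19.6 CPM and rpl-11.2 from 222 ± 14.9 to 487 ± 38.8 CPM, and rpl-25.2 and rpl-25.1 moved apart in the same way (log2 fold changes −0.98 and 1.04). By chromosome, the share of tested genes that rose was 66.7% on X and 59.8% on V, against 31.98% on I and 36.2% on III. The lincRNA genes had 32 of 50 higher and 5 lower.

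In the tests that follow, those of other splits, X-linked genes and gene length were planned before their results were seen, and those of the epidermis list, the immune and detoxification lists and the mitochondrial chaperones only after. The bootstrap intervals and permutation p-values among them resample genes, taken as independent, and not libraries. They do not measure the spread between pools. The 6 libraries have 10 splits into 3 and 3, too few for a share under 0.05. In 1 split, the real one, as many genes were higher (6927) and in 1 as many were lower (5990), and the highest other split gave 0 by edgeR, with at most 17 genes at an unadjusted p under 0.05. Each other split mixes the conditions, so the difference between them enters the spread within groups. Few calls could arise there, and no conclusion is drawn from the 0. For the lists, 6 splits gave as many as the 25 of the real one. The splits other than the real one gave 24 to 26, so the number of lists does not set the real grouping apart. Each other split still separates the libraries unequally by condition.

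Germline markers were lower and neuron, muscle, pharynx and intestine markers higher, a gap of 2.03 between the medians (95% bootstrap interval 1.89 to 2.29). A scaling factor shifts all genes of a library alike and leaves this gap as it is, and gene length does not account for it, as the gap was 2.02 once the length trend was removed. A smaller share of germline RNA in the worms may contribute: X-linked genes, few of which are expressed in the germline, had a median 0.737 above autosomal genes (interval 0.678 to 0.793, permutation p = 1e-04, the smallest possible), although autosome V, at a median of 0.669, lay near X at 0.746, and regulation within germ cells stays open. That share alone would raise all somatic markers, but the epidermis list lay below the 4 other somatic lists (difference of medians −1.593, interval −2.164 to −0.975, permutation p = 1e-04). Its members went both ways (13 lower, 7 higher) and a smaller share of embryo RNA and a change in the epidermis both stay open and untested, since the embryo list had a median of −2.34, or −0.418 with genes above 5 CPM alone, and a share of counts that went from 0.040% to 0.048%, or from 0.035% to 0.021% without sdz-27.

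Innate immune, intracellular pathogen response and xenobiotic lists were higher, and so were markers of the intestine, where many of these genes are expressed. Their medians differed from that of the intestine markers by −0.008 (interval −0.21 to 0.36), 0.206 (0.046 to 0.552) and 0.048 (−0.105 to 0.391). A smaller germline share and an induced response cannot be told apart for these lists, since a response of a like size could give the same medians. The intracellular pathogen response list had a permutation p of 0.0105 (0.0315 after adjustment over 6 comparisons), but neuron markers lay 0.257 above the intestine markers as well.

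Both mitochondrial chaperones fell. hsp-60 fell by more than any of 40 germline and oocyte markers, with a log2 fold change −0.706 from that of the lowest, htp-3, but car-1, a germline transcript outside that list, fell as far (−2.78 against −2.75). A smaller germline share is thus neither shown nor excluded for hsp-60. It also stays open for hsp-6, since 2 of the 40 markers fell more than hsp-6. A fall shared with other nuclear-encoded mitochondrial transcripts is not enough for both. hsp-6 lay −1.015 from the first quartile of 113 respiratory chain and mitochondrial ribosome genes, of which 0 fell more. Mitochondrial content itself was not measured, so no conclusion is drawn on it. Lower expression of these chaperones within cells may contribute, and a smaller share of embryo RNA was not tested as a cause.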
